A study of Mus musculus with 23 samples.

How the data were processed

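Single-cell RNA sequencing data of 23 samples were used, of which 8 came from sorted fibroblasts, 4 from sorted T cells with TCR sequences, 9 from the tumour microenvironment (TME) and 2 from the TME of mice labelled Tgfbr2 knockout or wild type under LysM. Per the labels, 10x Genomics kits were used, the 3-prime kit v3.0 for the TME and fibroblasts and the 5-prime kit v1.0 for T cells, and Cell Ranger 6.0.1 was run by the authors with the mouse genome mm10 (GRCm38). The deposited T cell and LysM tables hold raw UMI counts per gene and cell. The deposited fibroblast and TME tables hold whole numbers whose sum hardly differs between cells, so the authors had adjusted them to a common depth. These deposited values are treated here as a score adjusted by the authors and not as counts, and how the adjustment was made is not given in the sources used here. The tables held 18077 (fibroblast), 43377 (TME), 11662 (T cell) and 24529 (LysM) columns and 19582, 18120, 10776 and 16031 genes. The last line of the LysM table was cut short, so genes that would follow it were not analysed here. Of the LysM columns 17352 match no sample and were not used here.

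Treatments were read from the ending of each column name. Fibroblast libraries were told apart as runs of sorted barcodes within a treatment, and the columns do not tell which of the 2 sets a library belongs to. In the TME each set 1 library was 1 unit, and the cells of 1 treatment in both hashed libraries of set 2 were summed to 1 unit. The 3 further control libraries (set 3) were summed to 1 unit and used only as an alternative. Per the labels 1 of them is of line MTO140 and 2 are of MTO129, while their columns form only 2 runs of sorted barcodes, so the 3 could not be told apart. In the TME the endings of the column names number the sets in another order than the titles, and the sets were matched by the treatments that occur in them.

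Cells with at least 300 genes and under 20% mitochondrial values were kept. The LysM table holds no mitochondrial genes, so only the number of genes was used there. Each table was log-normalised and clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, leidenalg 0.10.2 with igraph 0.11.9 at resolution 1). Doublets were marked with Scrublet in each library and left out of all comparisons. It marked only 34 (fibroblast), 138 (TME), 11 (T cell) and 12 (LysM) cells, too few for the number of cells loaded, so leaving out the highest 5% of scores was added as an alternative. A cluster was named after a type when at least 3 of its markers, fixed before the data were examined, had a log2 fold of at least 1 over other cells and were found in at least 10% of cells, or else when at least 3 were found in at least 50% of cells, which in the T cell sort was the first rule. A cluster with at least 4 markers of a second, unrelated type, each in at least 50% of cells, was left unnamed. So was one led by markers of another type, and 1 with few values per cell and none of its markers among its 10 leading genes. These thresholds were chosen after the cells were seen, as were a check of the 10 leading genes of each cluster against cells of other named types and an exception for 2 clusters of the fibroblast sort (4 and 5). These stayed named fibroblast although 1 marker of pericytes or stellate cells and none of fibroblasts was among those 10 genes, because 8 of 9 fibroblast markers were each found in at least 50% of their cells. Against all other cells of the sort, the 10 leading genes of cluster 4 held 2 markers of smooth muscle and none of fibroblasts. T cells were divided into CD8, CD4 helper, regulatory and naive or central memory T cells in the same way.

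The values of each type were summed over the cells of a unit and scaled to 1000000 (CPM). Macrophage units held 1391 to 3118 cells and summed values of 6427366 to 15280137, T cell units 335 to 1603 cells and 1215814 to 6296805, and fibroblast libraries 491 to 3586 cells of that type and 4673549 to 33232120. A fit for counts had been planned and could not be used on depth-adjusted values. In its place the log2 of CPM plus 4 was fitted with limma 3.58.1 (R 4.3.3; lmFit and eBayes with a trend) for genes with a mean of at least 10 CPM, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each fit used all 4 treatments as groups of 2 units, or all 8 units as with (galunisertib alone or dual) against without (control or anti-PD-L1). The interaction was dual minus galunisertib minus anti-PD-L1 plus control. In T cells of the TME the planned comparisons were dual against control and with against without galunisertib. All adjusted p-values of genes are from limma and two-sided. Recovery was tested on simulated data, with 100 genes given a log2 fold change of 1 and 100 of 2, and wrong calls numbered 0 to 22 per fit. The simulated spread was drawn independently for each gene and unit, and a difference between sets was added only for fits with the set as a block. Recovery in the real data, where genes vary together, can differ.

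A total of 22 gene lists fixed before the data were examined were tested, and each is named where its result is given. They were tested where at least 3 of their genes were measured, with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the lists of a comparison. Where the report gives 2 adjusted p-values for a list, the first is from camera at the preset correlation and the second with an estimated correlation. Shares of 14 TME classes with at least 1 cell in every unit and a median of at least 30 cells per unit were compared by an exact two-sided permutation test of the mean logit share, with adjustment over the classes. The T cell and LysM libraries have no replicates, so no test was run there. Their values carry exact 95% intervals (Poisson for CPM, binomial for ratios and Clopper-Pearson for shares) that cover counting error only, with a floor of 3 counts for a count of 0, and lists were placed among 10000 random lists of like expression. Genes of the random lists were drawn independently, so these lists do not keep the correlation between genes. Clonotypes were the sets of productive TRA and TRB CDR3 nucleotide sequences, and diversity was taken at 1580 cells in 200 draws.

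Genes were named by a rule fixed before the data were examined. It takes the 10 largest rises and falls among called genes with a mean log2 CPM of at least 5 and the same sign in every set, or the 3 smallest p-values per direction where none was called, up to 4 members of each list by smallest p-value, and Spp1, Tgfbr2, Cd274 and Tgfb1. For single libraries it takes the 10 largest ratios with at least 100 counts in at least 5% of cells. Only part of the genes it allows is printed. Coordinates are from the RefSeq annotation of GRCm38 and were found for 461 of 462 genes looked up. Alternatives were another scaling, no filter on low values, the set as a block, each unit left out in turn, stricter cell filters, doublets kept, the set 3 controls added, each hashed library as its own unit, pseudocounts of 1 and 16, the highest 5% of doublet scores left out, doubtful clusters left out and fibroblast libraries blocked by their order. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.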

Results

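Single-cell RNA sequencing (scRNA-seq) was performed on cells sorted from mouse liver metastases. The metastases grew after colorectal tumour organoids of the lines MTO129 and MTO140 were injected into the spleen of C57BL/6J mice aged 7 to 8 weeks. The study asked how transforming growth factor beta (TGF-β) keeps T cells out of such metastases and limits the response to anti-PD-L1. Mice received galunisertib, an inhibitor of the type I TGF-β receptor kinase, at 800 mg/kg per dose by gavage from day 12 to 15 on, an antibody to PD-L1, both drugs (dual), or the control substances. A total of 23 samples were recorded. They were 8 of sorted fibroblasts (2 per treatment), 4 of sorted T cells with T cell receptor (TCR) sequences (1 per treatment), 9 of the tumour microenvironment (TME) and 2 of the TME from mice whose labels give a Tgfbr2 knockout or wild type under LysM, a Cre driver of myeloid cells. The 9 TME samples were 4 libraries of line MTO129 (set 1), 2 hashed libraries of line MTO140 that each held all 4 treatments (set 2), and 3 further control libraries (set 3). The labels do not say how many animals made each library, so the p-values below measure only the spread between these samples.

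After filtering, 17802 cells of the fibroblast sort, 41892 of the TME, 11144 of the T cell sort and 7177 of the LysM libraries were kept. The fibroblast libraries held 530 to 3878 cells and summed values of 5054736 to 35956714. The set 1 TME libraries held 3812 to 5692 cells and summed values of 18378373 to 27117416. In both tables these values had been adjusted for depth. The T cell libraries held 2773 (control), 2986 (anti-PD-L1), 2725 (galunisertib) and 2660 (dual) cells with 4141913, 6879202, 7089462 and 7512961 unique molecular identifiers (UMIs). The LysM libraries held 3959 (knockout) and 3218 (wild type) cells with 34160757 and 27833990 UMIs. Cells were named by marker genes, and each name stands for cells like that type. In the TME 19739 cells were named macrophage or monocyte, 8068 T, 4710 dendritic, 2952 neutrophil and 2287 B cells. In the fibroblast sort 16469 cells were named fibroblast-like.

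The first question was what galunisertib did to the cells around the tumour, with 4 units that received it set against 4 that did not. A unit was the cells of 1 treatment in 1 set. Macrophages or monocytes made up 36.9% ± 3.40 of cells with galunisertib and 54.9% ± 6.31 without (SD, n = 4 each). T cells made up 28.4% ± 6.83 and 12.8% ± 4.64. Regulatory T cells made up 4.57% ± 0.842 and 2.10% ± 0.429, and fibroblasts 0.508% ± 0.107 and 1.42% ± 0.419, from only 18 to 27 cells per unit with galunisertib. As a share of T cells regulatory T cells were 12.8% to 26.4% with and 12.7% to 21.9% without galunisertib, so their higher share of all cells goes with that of T cells. For each of these 4 classes all 4 units with galunisertib lay on the same side of all 4 without, and the exact two-sided permutation p was 0.0286, the smallest that 4 against 4 allows. Adjusted over the 14 classes tested it was 0.1, so no class passed the threshold. An adjusted value below it would need most of the 14 classes to reach the smallest p at once. That no class passed therefore does not show that the shares were unchanged. CD8 T cells made up 12.8% ± 7.69 with and 3.54% ± 3.57 without galunisertib (exact permutation p = 0.171, adjusted p = 0.343). Within each set both units with galunisertib lay above both without (16.6% and 17.1% against 6.35% and 6.89% in set 1, 1.25% and 16.2% against 0.313% and 0.591% in set 2). With labels permuted within each set p was 0.0556, the smallest that this allows (adjusted p = 0.111). The 4 classes above reached the same p in that test. So did endothelial cells (0.970% with and 1.71% without galunisertib) and T cells without a named subtype (6.11% and 3.69%). The control and anti-PD-L1 units of set 2 held only 29 and 13 CD8 T cells. Dendritic cells made up 11.7% ± 3.41 and 11.3% ± 0.667 (exact permutation p = 0.857). The T cell share was highest under dual treatment, at 32.5% in set 1 and 34.8% in set 2, against 26.7% and 19.5% with galunisertib alone, 16.4% and 9.59% in the controls and 17.1% and 8.06% with anti-PD-L1 alone. Shares of 1 sort rise and fall together, and the sort itself sets which cells are counted.

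**Figure D1:**
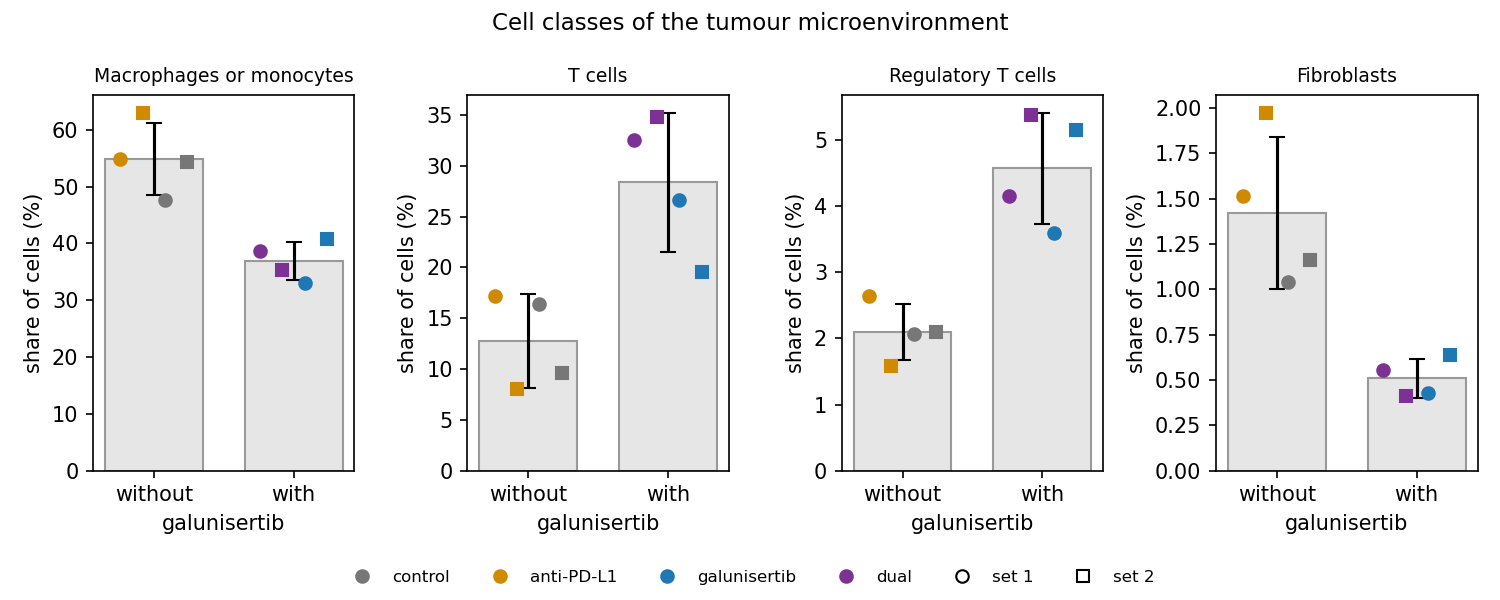
Share of cells (%) of macrophages or monocytes, T cells, regulatory T cells and fibroblasts in each of the 8 TME units, by treatment and set, with the mean of 4 units with and of 4 without galunisertib as bars and the SD as lines. In the 4 units with galunisertib T cells averaged 28.4% and macrophages 36.9%, against 12.8% and 54.9% in the 4 without.

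Macrophages of mice given galunisertib had lower expression of TGF-β receptors and TGF-β targets and higher expression of Il6, Klf2 and Vcam1 among others. Values are CPM, the depth-adjusted values scaled to a sum of 1000000 in each unit. With against without galunisertib, limma called 130 of 7910 genes, 38 up and 92 down. Pmepa1 (chromosome 2, 173224458 to 173276731, GRCm38), a target of TGF-β whose protein holds its signalling back, fell from 155 ± 37.5 to 12.8 ± 4.02 CPM (log2 fold change -3.23, SE 0.20, adjusted p = 0.000134, n = 4 each). F11r (chromosome 1, 171437561 to 171464593), which encodes the junctional adhesion molecule JAM-A, fell from 121 ± 11.7 to 20.9 ± 5.41 (-2.35, SE 0.15, adjusted p = 0.000134). Tgfbr1 (chromosome 4, 47353222 to 47414926), the receptor whose kinase galunisertib blocks, fell from 151 ± 31.9 to 39.2 ± 6.79 (-1.84, SE 0.17, adjusted p = 0.00101), and its partner Tgfbr2 from 55.5 ± 3.45 to 34.7 ± 5.24 (-0.63, SE 0.12, adjusted p = 0.0337). Skil, a co-repressor of SMAD proteins that TGF-β induces, fell from 320.1 ± 28.7 to 144 ± 39.9 (-1.17, adjusted p = 0.0208).

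Other genes fell as well. Slamf9, a receptor of the SLAM family, fell by 1.70 log2 units (adjusted p = 0.000401), Spint1, an inhibitor of serine proteases, by 1.56 (adjusted p = 0.000546), Zmynd15 by 1.74 (adjusted p = 0.000861) and Sgk1 by 1.59 (adjusted p = 0.0208). Havcr2, which encodes the checkpoint receptor TIM-3, fell from 116 ± 9.00 to 40.2 ± 6.06 (-1.45, adjusted p = 0.000564). Cx3cr1, the fractalkine receptor, fell from 247 ± 34.8 to 89.5 ± 21.6 (-1.44, adjusted p = 0.00991). Cxcl16, the ligand of the chemokine receptor CXCR6 of T cells, fell from 739 ± 52.1 to 344 ± 95.2 (-1.13, adjusted p = 0.021). Apoe fell from 7280.1 ± 1624 to 2914 ± 941 (-1.35, adjusted p = 0.0295), C1qa, a subunit of complement C1q and a marker by which these cells were named, from 3038 ± 442 to 1718 ± 239.5 (-0.82, adjusted p = 0.0371), and the tetraspanin gene Cd9 by 1.02 (adjusted p = 0.0371). The mix of macrophage clusters differed too. Cluster 12 was led by Pf4, Ccl24 and Gpnmb, and Spp1 was among its 10 leading genes against all other cells. It held 1.98% and 2.66% of macrophages with galunisertib against 0.26% and 0.577% without in set 1. In set 2 it held 19.2% and 22.1% against 6.26% and 7.94%. Cluster 2, with C1qc, C1qa and Apoe among its leading genes, held 15.7% and 21.4% against 26.4% and 34.9% in set 2, and in set 1 its shares with galunisertib (6.97% and 8.81%) overlapped those without. Without cluster 12, 119 genes were called and C1qa was not (log2 fold change -0.77, adjusted p = 0.0686). The summed values do not separate a change within cells from a change in this mix.

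Among the genes that rose were cytokine, adhesion and scavenger genes. Il6 rose from 9.97 ± 3.32 to 61.5 ± 30.6 (2.12, SE 0.35, adjusted p = 0.0188) and Klf2, a transcription factor that restrains inflammation, from 121 ± 23.7 to 442 ± 191 (1.75, SE 0.29, adjusted p = 0.0173). Vcam1, which binds the integrin VLA-4 on lymphocytes, rose from 49.7 ± 8.93 to 135 ± 31.3 (1.37, SE 0.18, adjusted p = 0.00871). Ccl9, a chemokine, rose by 1.13 (adjusted p = 0.0169), Cd38, an enzyme that consumes NAD, by 1.13 (adjusted p = 0.0262), Sdc4 by 1.12 (adjusted p = 0.0272), Clec4e, the receptor Mincle, by 1.11 (adjusted p = 0.0172) and Thbs1, which encodes thrombospondin 1, by 1.02 (adjusted p = 0.0356). Dok2 rose by 0.96 (adjusted p = 0.0173), Cfp, which encodes properdin, by 0.93 (adjusted p = 0.0152) and Mrc1, the mannose receptor, by 0.93 (adjusted p = 0.0106). Spp1 (chromosome 5, 104435111 to 104441053), the osteopontin gene that marks SPP1 macrophages, had a log2 fold change of -1.44 (SE 0.48, 204 ± 80.4 against 639 ± 439) that did not pass (adjusted p = 0.268), and it passed with the set as a block (adjusted p = 0.00123). Cluster 12, with Spp1 among its leading genes, was a larger share of macrophages with galunisertib in both sets. The lower summed value of Spp1 thus does not show that SPP1 macrophages were fewer. With the set as a block 727 genes were called, 360 up and 367 down, among them all 130. Without the anti-PD-L1 unit of set 2 the count was 31, without the dual unit of set 2 it was 37, without the control unit of set 1 it was 50, without that of set 2 it was 59 and without the galunisertib unit of set 2 it was 84. With any 1 unit left out, 10 of the 26 called genes named here stayed past the threshold (Pmepa1, F11r, Tgfbr1, Slamf9, Spint1, Zmynd15, Havcr2, Cx3cr1, Vcam1 and Mrc1), and each of the other 16 lost it without 2 to 7 of the 8 units. The effect of galunisertib differed between the sets in 0 of 7910 genes by limma (535 at an unadjusted p below 0.05), a test that was not planned. The count of 535 is above what chance alone would give, and each set held only 2 units on each side. The count of 0 therefore does not show that the effect was the same in both sets.

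**Figure D2:**
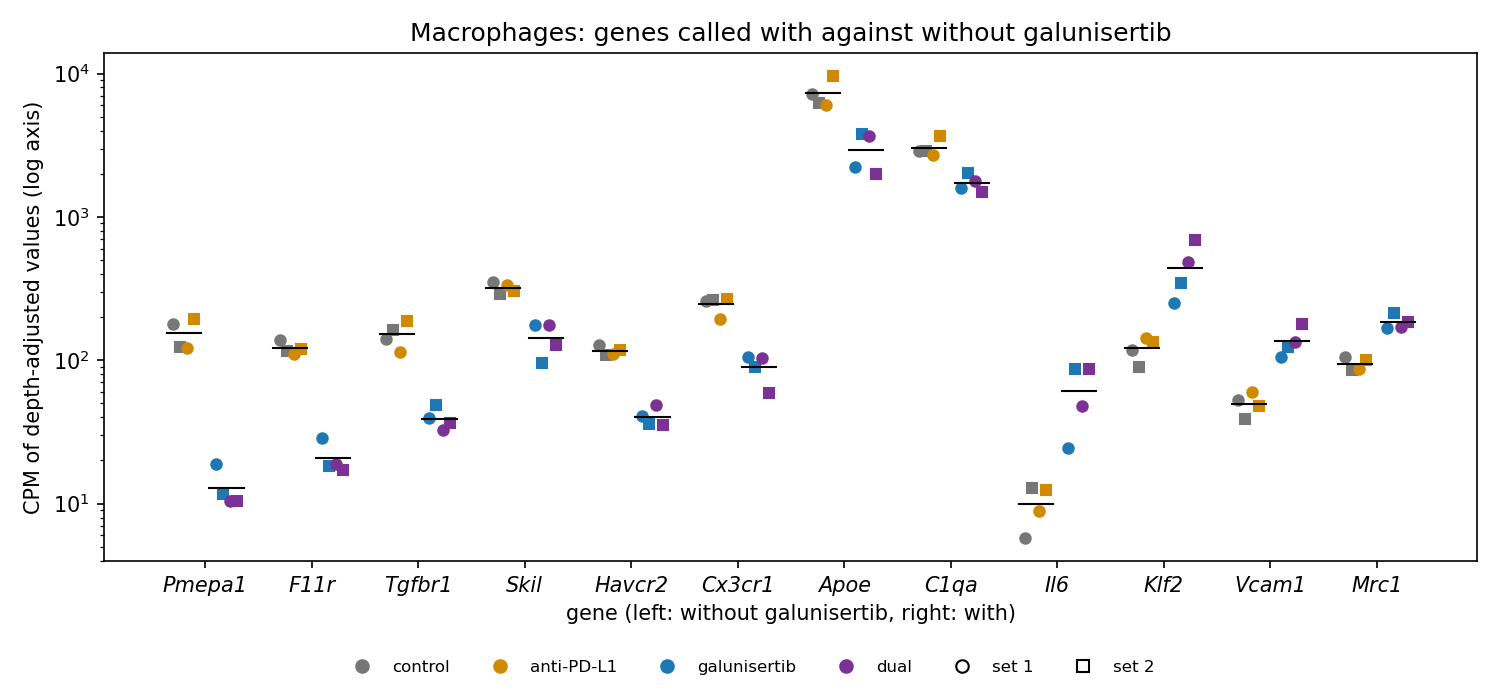
Expression in CPM of depth-adjusted values (log axis) of 12 genes called in macrophages with against without galunisertib, as points for each of the 8 TME units by treatment and set, with the mean of each 4 units as a line. Pmepa1 averaged 12.8 with and 155 without galunisertib, and Vcam1 135 and 49.7.

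Of the 18 gene lists measured in macrophages, 8 passed camera at its preset correlation, none passed with an estimated correlation, and 3 passed fry. All 7 measured TGF-β targets were lower with galunisertib (median -0.69; camera adjusted p = 1.49e-06, adjusted p = 0.22 with an estimated correlation; fry adjusted p = 0.036), of which 2 fell over all genes tested and 4 adjusted over the list alone. The 6 inflammatory fibroblast genes were all higher (median 0.86; camera adjusted p = 0.00843, 0.22 with an estimated correlation; fry 0.049), and the checkpoint and exhaustion list had 4 of 6 lower (median -0.32; 0.0475 and 0.334; fry 0.049). All 7 MHC class II genes were lower (median -0.37; 0.00112 and 0.528), as were all 5 fibrillar collagen and matrix genes (median -0.44; 0.00804 and 0.334) and 7 of 10 T cell trafficking genes (median -0.19; 0.0413 and 0.589). Fibroblasts were a smaller share of these units with galunisertib (0.508% against 1.42%). Whether the matrix genes in macrophages came from free RNA of fibroblasts was not tested. Inflammatory cytokines had 9 of 12 higher (median 0.54; 0.0107 and 0.589), and hypoxia and glycolysis 10 of 13 (median 0.30; 0.0108 and 0.589). Adjusted over the list alone 3 genes each passed of the cytokine, checkpoint and trafficking lists and 2 of the hypoxia list, against 1, 1, 1 and 0 over all genes. With the set as a block the checkpoint and trafficking lists no longer passed camera (adjusted p = 0.0522 and 0.0836), and the MHC class II and trafficking lists passed fry (0.00727 and 0.0418). The SPP1 macrophage list had 10 of 18 genes higher, a median of 0.05, a mean of -0.08 and a camera direction of down (adjusted p = 0.868), so it moved in no 1 direction. The C1q macrophage list had 7 of 10 lower (median -0.44, adjusted p = 0.0678, and with the block it passed at a value that rounds to 0.05) and the inflammatory monocyte list 7 of 10 higher (median 0.13, adjusted p = 0.868).

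Galunisertib alone was then compared with control, 2 units each. Pmepa1 fell from 151 ± 40.3 to 15.2 ± 5.06 CPM (log2 fold change -3.02, SE 0.30), F11r from 128 ± 14.9 to 23.7 ± 7.43 (-2.27, SE 0.22) and Spsb1, which encodes an adaptor of a ubiquitin ligase and was outside the rule for naming genes and chosen after its values were seen, by 1.93 (limma adjusted p = 0.047 for each). These 3 were all the genes called, and with any of the 8 units left out none was. Havcr2 had a log2 fold change of -1.53 (adjusted p = 0.141) and Klf2 of 1.48 (adjusted p = 0.334), and both passed with the set as a block (adjusted p = 0.000882 and 0.00762), in which 290 genes were called, 102 up and 188 down. All 7 TGF-β targets were lower (median -0.68; camera adjusted p = 1.84e-11, 0.304 with an estimated correlation; fry adjusted p = 0.222, and 0.019 with the block), 3 of them adjusted over the list alone and 1 over all genes. All 7 MHC class II genes were lower too (median -0.44; 0.000517 and 0.468).

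In dual treatment against control the same leading genes changed. Pmepa1 fell to 10.4 ± 0.0259 CPM (log2 fold change -3.40, SE 0.30) and F11r to 18.1 ± 1.12 (-2.57, SE 0.22), with a limma adjusted p of 0.0312 for each, and no other gene was called. Klf2 stood at 587 ± 147 against 104 ± 21.0 (2.44, SE 0.27, adjusted p = 0.0536) and Il6 at 67.6 ± 27.4 against 9.27 ± 4.97 (2.43, SE 0.55, adjusted p = 0.353). Both passed with the set as a block (adjusted p = 0.000483 and 0.00127), which called 530 genes up and 579 down. Without either control unit or either dual unit no gene was called, and without either anti-PD-L1 unit 5 were. Inflammatory cytokines had 11 of 12 genes higher (median 0.99; camera adjusted p = 0.00105, 0.494 with an estimated correlation), of which 2 passed adjusted over the list alone and 0 over all genes. Dissociation and stress genes were higher in 10 of 13 cases (median 0.40; 0.041 and 0.494), and the inflammatory monocyte list had 8 of 10 lower (median -0.31; 0.041 and 0.494).

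Anti-PD-L1 alone left no gene of macrophages past the threshold. Limma called 0 genes, and 10 had an unadjusted p below 0.05. The inflammatory monocyte list had 9 of 10 genes lower (median -0.23; camera adjusted p = 0.000109, 0.164 with an estimated correlation). For the interaction of galunisertib and anti-PD-L1 limma called 0 genes with 19 at an unadjusted p below 0.05. The counts of 10 and 19 genes are below what chance alone would give. These fits leave the spread between sets in their error, so the counts do not show a lack of effect. The largest departure from adding the effects was Mid1, a ubiquitin ligase gene (log2 1.92, SE 0.24, adjusted p = 0.577), the only gene called with the set as a block (adjusted p = 0.0223). All 11 proliferation genes had a negative interaction (median -0.50; camera adjusted p = 1.02e-06, 0.387 with an estimated correlation).

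In T cells of the TME, Pmepa1 again led. With against without galunisertib it fell from 146 ± 40.8 to 29.8 ± 5.79 CPM (log2 fold change -2.13, SE 0.23, limma adjusted p = 0.0248, n = 4 each) and was the only gene called of 7961. With the set as a block 72 genes were called, 21 up and 51 down. Among these Itgae (chromosome 11, 73090505 to 73147449), which encodes the integrin CD103 of tissue-resident T cells, stood at 22.0 ± 11.1 against 104 ± 36.4 (-2.14, SE 0.41, adjusted p = 0.306, block adjusted p = 0.00494) and Skil at 96.4 ± 54.2 against 249 ± 50.1 (-1.49, SE 0.37, adjusted p = 0.856, block adjusted p = 0.00172). Gzmb, the granzyme B gene, stood at 527 ± 373 against 173 ± 61.3 (1.44, SE 0.41, adjusted p = 0.972). Without the anti-PD-L1 unit of set 2 the count was 3, and without any other unit it was 0. The units of set 2 held few CD8 T cells except in dual treatment, at 46.4% of T cells against 6.42% with galunisertib, 6.16% in control and 3.88% with anti-PD-L1. In set 1 CD8 T cells were 52.4% (dual) and 62.4% (galunisertib) of T cells, against 42.1% in control and 37.0% with anti-PD-L1. T cells without a named subtype were 22.2% in dual treatment, 55.6% with galunisertib, 54.4% in control and 66.6% with anti-PD-L1 in set 2, and 8.41% to 16.7% in set 1, so some CD8 T cells of set 2 can be among those.

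Of the 18 lists measured in these T cells 11 passed camera at the preset correlation, and none passed with an estimated correlation or in fry. All 6 TGF-β targets were lower with galunisertib (median -0.77; camera adjusted p = 6.11e-11, 0.0733 with an estimated correlation), of which 1 fell over all genes and 3 adjusted over the list alone; with the set as a block the estimated correlation gave an adjusted p of 0.0161 and fry one of 0.000472. All 13 proliferation genes were higher (median 0.80; 1.93e-07 and 0.228) and 9 of 12 cytotoxic genes too (median 0.46; 0.0142 and 0.199). Naive and central memory genes had 7 of 10 lower (median -0.36; 0.00448 and 0.289), chemokines for T cells 5 of 6 (median -0.35; 0.04 and 0.182, and 0.103 with the block), and all 6 MHC class II genes were lower (median -0.63; 8.3e-09 and 0.141). Macrophage RNA at the share that C1qa gives would supply 68.5% of the class II partner Cd74 in T cells without galunisertib. Regulatory T genes had 6 of 10 lower (median -0.05) and did not pass (0.141). For all these lists the summed values do not separate a change within cells from a change in the mix of T cell subtypes. Genes of the C1q macrophage list were lower in all 7 cases (median -0.53; 8.01e-06 and 0.188), and C1qa stood in T cells at 3.39% of its level in macrophages. In dual treatment against control limma called 0 genes and 73 had an unadjusted p below 0.05. That is fewer than chance alone would give, and this fit leaves the spread between sets in its error. The block called 15, 4 up and 11 down, among them Ccl1, a chemokine gene, at 165 ± 48.2 against 790.0 ± 41.3 (-2.26, SE 0.49, adjusted p = 0.999, block adjusted p = 0.0448), Nt5e, which encodes the ectoenzyme CD73, at 62.8 ± 29.7 against 192 ± 43.9 (-1.61, block adjusted p = 0.0123) and Serpinb6b at 251 ± 18.5 against 67.1 ± 19.5 (1.87, block adjusted p = 0.0409). On simulated data this comparison recovered 9% of genes with a log2 fold change of 2, and 88% with the block.

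In fibroblasts the question was whether galunisertib lowered the matrix genes that TGF-β drives. Fibrillar collagen and matrix genes were lower with galunisertib in 14 of 16 cases (median -0.47; camera adjusted p = 4.98e-11, 0.35 with an estimated correlation), 2 of them adjusted over the list alone and 0 over all genes. All 12 proliferation genes were higher (median 0.80; 6.56e-12 and 0.35), 11 of them adjusted over the list alone and 0 over all genes. All 12 type I interferon genes (median 0.40; 0.000314 and 0.639) and all 16 interferon gamma genes (median 0.60; 0.0229 and 0.72) were higher. In the fibroblast sort cluster 1, with Gbp4 and Cxcl9 among its leading genes, had 57.4% of its cells from 1 library. For all lists in fibroblasts the summed values do not separate a change within cells from a change in the mix of clusters. No list passed fry, and in no fibroblast comparison did any gene pass over all 8469 tested. These fits hold no term for the difference between libraries along the first principal component (53.1% of the variance), so the count of 0 does not show that no gene changed. A fit with the libraries blocked by their order in the table called 135 genes with against without galunisertib (66 up and 69 down), but no column name gives the set of a library and no call here rests on that order. In limma 0 genes were called with against without galunisertib and 451 had an unadjusted p below 0.05. The nearest were Fxyd6, which encodes a regulator of the sodium pump, at 28.6 ± 1.63 against 65.1 ± 7.45 CPM (log2 fold change -1.08, SE 0.13, adjusted p = 0.0739, n = 4 each), Lpl, the lipoprotein lipase gene, at 240.3 ± 26.8 against 627 ± 149 (-1.34, SE 0.19, adjusted p = 0.121) and Abcc9, a potassium channel subunit gene of pericytes, at 96.7 ± 21.8 against 43.6 ± 9.87 (1.08, SE 0.21, adjusted p = 0.296). The matrix gene Bgn, which encodes biglycan, stood at 2945 ± 336 against 4449 ± 309.6 (-0.60, SE 0.15, adjusted p = 0.585). Spp1 stood at 1829 ± 1448 against 6029.8 ± 4006 (-1.90, SE 0.73, adjusted p = 0.833). TGF-β targets had 7 of 11 lower (median -0.22, adjusted p = 0.206), contractile genes 8 of 10 (median -0.15, adjusted p = 0.134) and basement membrane genes 6 of 9 (median -0.13; 0.0279 and 0.35). MHC class I genes were higher in all 8 cases (median 0.34, adjusted p = 0.136).

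**Figure D3:**
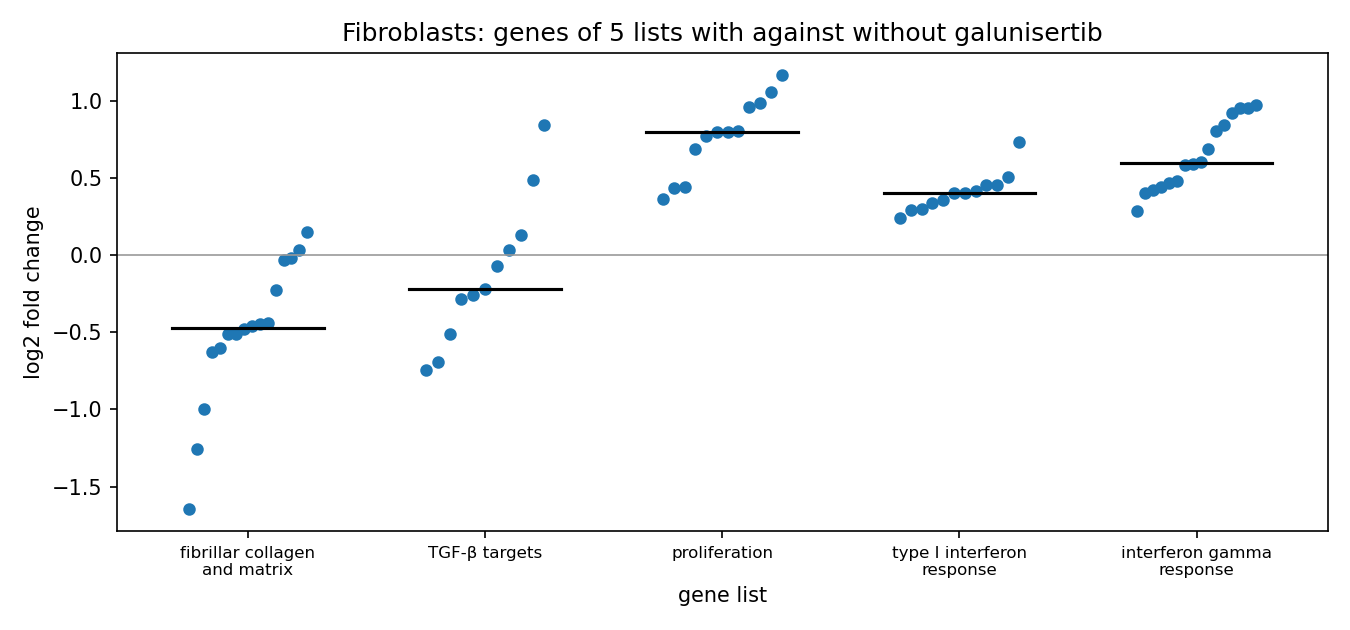
Log2 fold change of each gene (points) of 5 gene lists in fibroblasts, with against without galunisertib, 4 libraries each, with the median of each list as a line. The matrix list had a median of -0.47 and the proliferation list of 0.80, and no single gene passed over all genes tested.

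Each treatment of fibroblasts was also compared with control. With galunisertib alone limma called 0 genes (121 at an unadjusted p below 0.05). Rgs5, a regulator of G proteins in pericytes, stood at 98.0 ± 4.46 against 28.5 ± 3.22 CPM in control (log2 fold change 1.65, SE 0.23, adjusted p = 0.77, n = 2 each), and 13 of 16 matrix genes were lower (median -0.44; camera adjusted p = 6.55e-08, 0.636 with an estimated correlation). With anti-PD-L1 alone it called 0 genes (69 at an unadjusted p below 0.05). The chemokines for T cells were higher in all 6 cases (median 0.95; 0.00726 and 0.858), and Ston1, an endocytosis gene, stood at 23.4 ± 3.57 against 40.0 ± 5.09 (-0.69, adjusted p = 1). With dual treatment it called 0 genes (174 at an unadjusted p below 0.05). Lcn2, which encodes the iron carrier lipocalin 2, stood at 202 ± 119 against 23.8 ± 6.58 (2.78, SE 0.71, adjusted p = 0.998), all 16 interferon gamma genes were higher (median 1.09; 6.84e-05 and 0.517), and all 6 chemokines for T cells too (median 1.69; 3.14e-05 and 0.463). For the interaction it called 0 genes (10 at an unadjusted p below 0.05). Anpep, which encodes the peptidase CD13, had the smallest p (log2 -0.91, SE 0.28, adjusted p = 1), and 9 of 12 type I interferon genes had a positive interaction (median 0.26; 0.00105 and 0.932). On simulated data 72% of genes with a log2 fold change of 1 were recovered in the comparison of 4 against 4 libraries, and 16% in that of 2 against 2. Those data lacked the difference that the real libraries share across genes, so recovery in the real fits can differ. The counts of 121, 69, 174 and 10 genes are below what chance alone would give. Since these fits hold no term for the difference between libraries, they do not show a lack of effect.

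The T cell sort of line MTO129 held 1 library per treatment, so its values have no replicate and carry exact intervals for counting error only. CD8 T cells were 50.1% (95% interval 48.2 to 52.0) of cells in control, 37.3% (35.6 to 39.1) with anti-PD-L1, 47.0% (45.1 to 48.9) with galunisertib and 45.3% (43.4 to 47.2) in dual treatment. Regulatory T cells were 7.25% (6.32 to 8.28), 13.2% (12.0 to 14.4), 3.60% (2.93 to 4.37) and 7.91% (6.91 to 9.00) in the same order. Set 1 of the TME is of the same line. There regulatory T cells were 12.7%, 15.4%, 13.5% and 12.8% of T cells, and CD8 T cells 42.1%, 37.0%, 62.4% and 52.4%. The low regulatory share with galunisertib was thus not seen in the TME sort. Nor was the higher CD8 share with galunisertib of the TME sort seen in the T cell sort. In CD8 T cells Itgae stood at 116 CPM in control, 103 with anti-PD-L1, 19.2 with galunisertib and 8.15 in dual treatment. Against control its log2 ratio was -2.59 (-2.96 to -2.23) with galunisertib and -3.83 (-4.38 to -3.31) in dual treatment, and against the anti-PD-L1 library -2.42 (-2.78 to -2.07) and -3.66 (-4.21 to -3.15). Ccl1 stood at 398, 292, 98.2 and 64.5 CPM in the same order. Gzmb, also a marker by which CD8 T cells were named, stood at 362 CPM in control and at 1088, 1040.3 and 1366 in the other libraries. The control library stood apart from the other 3 in many genes, and its CD8 T cells lay mostly in 1 cluster (cluster 5) that held few of the others. Of its cells there with a clonotype, 51.0% were of 1 clone and 70.1% of the 3 largest. Itgae was among the leading genes of that cluster. Without that cluster the ratios of Itgae against control were -2.06 (-2.53 to -1.59) and -3.34 (-3.99 to -2.72). Among its 10 leading genes against other subtypes, cluster 5 held 1 marker of CD8 and 1 of gamma delta T cells, and it stayed named CD8. Cluster 1 (1746 cells) held 1 gamma delta marker and no CD8 marker there, and it got no subtype. Some CD8 T cells can be among its cells, so the shares of CD8 T cells above rest on this naming. The control library had a median of 1295 UMIs per CD8 T cell against 2184 to 3155 in the others. Of the CD8 T cells with a clonotype, the largest clone held 42.6% in control and 37.4% with anti-PD-L1. With galunisertib it held 43.4% and in dual treatment 15.7%. The values of CD8 T cells thus also compare different clones, which the intervals do not cover.

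Against the anti-PD-L1 library, 4 of 5 TGF-β targets were lower in CD8 T cells with galunisertib (median -0.35, percentile 0.22 among 10000 random lists of like expression), 5 of 5 naive and central memory genes were lower (median -0.97, percentile 0) and MHC class I genes were higher (median 0.35, percentile 99.95). In dual treatment all 13 proliferation genes were higher (median 0.43, percentile 100) and 10 of 12 checkpoint and exhaustion genes were lower (median -0.29, percentile 0.04). The random lists were drawn gene by gene, so the percentiles do not allow for genes of a list that move together.

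Clones of T cells were counted from the TCR sequences. Of the cells with a clonotype, 74.2% (95% interval 72.0 to 76.4) belonged to clones of at least 2 cells in control, 66.4% (64.2 to 68.5) with anti-PD-L1, 69.0% (66.8 to 71.2) with galunisertib and 76.8% (74.8 to 78.8) in dual treatment, from 1580, 1856, 1710 and 1790 cells. The largest clone held 26.6% (24.5 to 28.9), 17.9% (16.2 to 19.8), 28.4% (26.2 to 30.6) and 10.8% (9.44 to 12.4) of these cells. At 1580 cells in each library the inverse Simpson index was 12.2, 27.1, 10.4 and 42.3, highest in dual treatment. The number of clonotypes at 1580 cells ranked otherwise, at 490, 691, 579 and 523, highest with anti-PD-L1. The 10 largest clones held 51.8%, 31.9%, 55.6% and 35.9% of cells in the same order, lowest with anti-PD-L1. By the TRB CDR3 alone the largest clone held 31.5%, 18.8%, 44.4% and 12.3%, and the inverse Simpson index was 8.70, 23.9, 4.94 and 28.8. CD8 T cells were in expanded clones in 83.1% to 91.3% of cases and naive or central memory T cells in 0.775% to 2.83%.

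**Figure D4:**
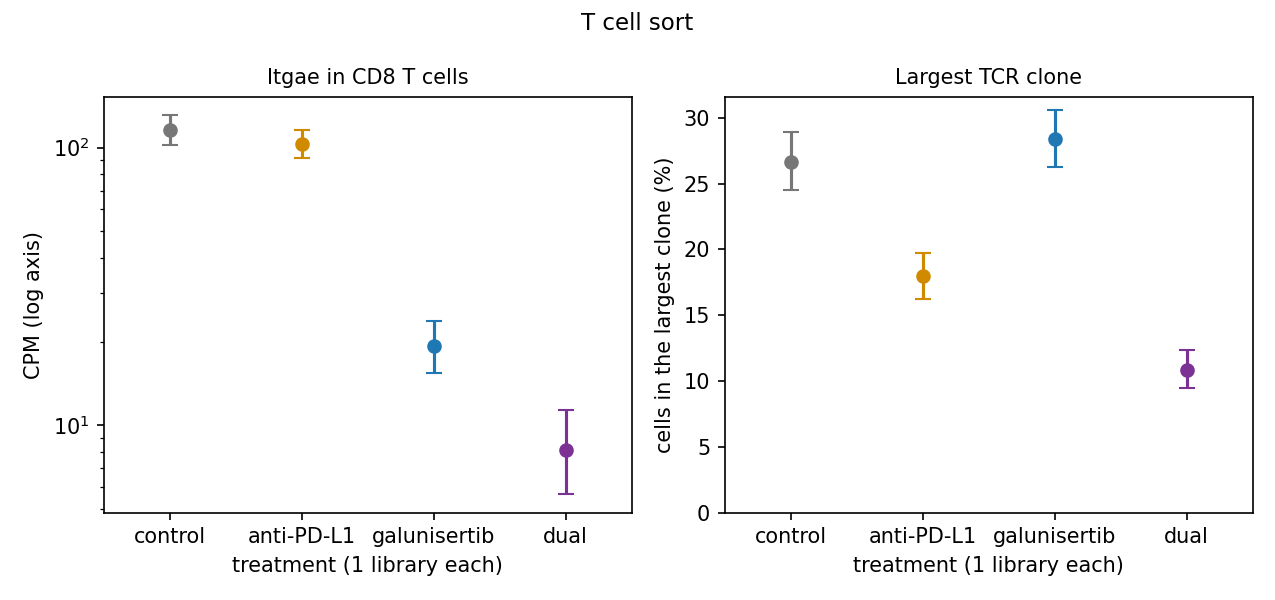
Values of the 4 T cell libraries (1 per treatment) with exact 95% intervals for counting error. The left panel gives CPM of Itgae in CD8 T cells on a log axis (116 in control and 8.15 in dual treatment), and the right panel the share of cells in the largest clone in percent (26.6% and 10.8%).

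Macrophages were compared between the library labelled Tgfbr2 knockout (1714 cells) and that labelled wild type (1836 cells), 1 library each. Apoe (chromosome 7, 19696244 to 19701310) stood at 1064 against 7713 CPM (log2 ratio -2.86, 95% interval -2.88 to -2.83), C1qb at 1454 against 3049 (-1.07, -1.09 to -1.05) and Selenop, a selenium carrier gene of resident macrophages, at 86.0 against 284 (-1.72, -1.81 to -1.63). Spp1 stood at 348 against 670.0 (-0.94, -0.99 to -0.90) and Tgfbi, a TGF-β target, at 472 against 867 (-0.88, -0.92 to -0.84). Higher in the library labelled knockout were Magi1, a scaffold protein gene (308 counts against 1), Sema7a (2.66), Ccl22, a chemokine that draws regulatory T cells (2.35), Il6 (1.75), Nos2 (1.48) and the elastase gene Mmp12 (1.26, 1.23 to 1.30). Tgfbr2 itself stood at 106 against 80.5 CPM (0.39, 0.29 to 0.50), so it was not lower in the library labelled knockout, and the reads do not tell whether they include the deleted part. The C1q macrophage list had 8 of 9 genes lower (median -0.80, percentile 0 among 10000 random lists), the inflammatory monocyte list 8 of 10 (median -0.55, percentile 0) and the type I interferon list 8 of 9 (median -0.48, percentile 0). The SPP1 macrophage list had 8 genes up and 8 down (median 0.04, percentile 45.9) and TGF-β targets 3 and 3 (median -0.02, percentile 22.3). None of these percentiles allows for genes of a list that move together. Macrophages were 43.4% (41.8 to 45.0) of cells in the library labelled knockout and 57.1% (55.4 to 58.8) in that labelled wild type, and T cells 6.71% (5.95 to 7.53) and 3.23% (2.65 to 3.91). In both libraries together 1378 cells were left unnamed, which can move these shares and which the intervals do not cover. Macrophages of the library labelled wild type lay mostly in clusters 1 and 6 and those of the library labelled knockout in clusters 2 and 4.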

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

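The counts over other splits of the samples, the test of Pmepa1 in T cells and both tests of the control T cell library were chosen only after the results were seen.

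Of 100 groups of 4 units looked at, 6 held a unit far from the other 3, and chance alone marks about 1 in 20. CD8 T cells were 1.25% of cells in the galunisertib unit of set 2 and 16.2% to 17.1% in the other units with galunisertib. In macrophages of the galunisertib unit of set 1 Pmepa1 stood at 18.8 CPM against 10.4 to 11.6 in the other 3, and F11r at 28.9 against 17.3 to 18.9. Cx3cr1 stood at 195 CPM in macrophages of the anti-PD-L1 unit of set 1 against 260.3 to 267 in the other units without galunisertib. In T cells Itgae stood at 5.53 CPM in the galunisertib unit of set 1 against 25.6 to 29.2, and Gzmb at 1086 in the dual unit of set 2 against 319.8 to 358.

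The 8 units can be split into 4 and 4 in 35 ways. For macrophages with against without galunisertib 2 splits called as many genes as the real one, which called 130, and the other was the split by set with 3439. For T cells 2 splits did, with 1 gene for the real one and 4936 for the split by set. For fibroblasts, with 0 genes called, all 35 did, and the highest count was 1551 for the split along the first principal component, which held 53.1% of the variance. The set, or a like difference between fibroblast libraries, thus moved more genes than galunisertib. Among the 18 splits with 2 units of each set on both sides, fitted with the set as a block, only the real one (1 split) called 727 genes in macrophages and 72 in T cells, and the highest of the others called 0 and 1. With 18 splits no share under 0.05 can be reached, so chance cannot be told apart there.

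Genes of the C1q list were lower in T cells with galunisertib, and free RNA of macrophages may be their source. C1qa, C1qb, C1qc and Apoe had a median log2 fold of -0.61 in T cells and of -0.78 in NK and B cells, types that should lack them, and the bound for this explanation, written before the test, was met. At the share of free RNA that C1qa gives, macrophage RNA would supply 94.6% of C1qb and 90.4% of Apoe in T cells without galunisertib. The same share would supply 3.58% of Pmepa1 there (5.23 of 146 CPM), which argues against free RNA as the source of the Pmepa1 that fell. The same share would supply 68.5% of Cd74 in T cells, and Cd74, H2-Aa, H2-Ab1 and H2-Eb1 were lower with galunisertib in NK cells (log2 -0.53 to -0.87) and neutrophils (-0.60 to -0.65) too, so free RNA stays open as a source of the fall of class II genes in T cells. In macrophages themselves C1qa, C1qb, C1qc and Apoe had a median log2 fold of -0.74, and these class II genes had log2 folds of -0.35 to -0.47. Less free RNA can thus come from this lower level, from the lower share of macrophages with galunisertib or from both. The bound that was met does not tell these apart.

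The control library of the T cell sort had few UMIs of many genes that the other 3 libraries held. Its CD8 T cells lay mostly in 1 cluster, but in naive or central memory T cells, which that cluster does not hold, 57 genes were over 4-fold higher in the median of the other 3 libraries, which argues against that cluster as the cause. The 105 genes over 4-fold higher in all 3 other libraries in CD8 T cells were all higher in CD4 helper and regulatory T cells, and 95.2% of them in naive or central memory T cells, and the lowest of the 3 medians was 2.07 in log2. A difference in making or sequencing that library could give this, and it is confounded with the treatment, since there is 1 library for each. A biological explanation, a lack of both drugs, was not tested apart from it.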

How the results depend on the processing

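The alternatives with pseudocounts of 1 and 16, with the highest 5% of doublet scores left out, with clusters led by a marker of another type left out without CD8 cluster 5 and with fibroblast libraries blocked by their order were chosen only after the data were seen. Where no cause is given, the cause was not tested.

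The genes run under an alternative kept their direction there, as did macrophages, T cells, regulatory and CD8 T cells and fibroblasts among the classes. The difference of dendritic cells, 0.0156 in logit share, changed sign under 6 alternatives, and those of B, NK and plasmacytoid dendritic cells did when single units were left out. Genes in neutrophils, dendritic, NK and B cells and the comparison of the LysM libraries with galunisertib were not run under any. Under median-of-ratios scaling 16 of 226 list medians changed sign, none of them named in the report for that comparison and none above 0.11 in size in log2 in the main scaling. The largest move among them was that of the inflammatory fibroblast list for the interaction in macrophages, from -0.07 to 0.27. Of the values of single genes and classes under alternatives, 930 stayed on their side of the threshold or within their interval, 144 lost it, 29 gained it and 7 moved outside their interval. Of 144 losses 116 came from leaving out 1 unit, where fewer samples were fitted and a lone unit is assumed to vary like the other groups.

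The set as a replicate block raised the number of genes called from 130 to 727 in macrophages with against without galunisertib, from 3 to 290 for galunisertib alone, from 2 to 1109 for dual treatment and from 0 to 1 for the interaction, and in T cells from 0 to 15 for dual treatment and from 1 to 72 with against without. The block takes out the spread between sets, and the departures of the units of set 1 from their treatment means correlated across genes at 0.70 to 0.81 in macrophages and 0.60 to 0.80 in T cells. It changed no other call of a gene count. No paired analysis was possible because the columns of the fibroblast table do not tell which library belongs to which set, so a pairing would rest on order or on the values. The first principal component parts the same libraries as the order does. A block by the order of the libraries in the table gave 3 genes for galunisertib alone, 0 for anti-PD-L1, 19 for dual treatment, 135 with against without galunisertib and 0 for the interaction. It passed Rgs5 for galunisertib alone and Fxyd6, Lpl, Abcc9 and Spp1 with against without, and no call rests on it. Each hashed library as its own unit gave 491, 108, 265 and 1 genes in macrophages and 2 and 13 in T cells in the same order. These units hold cells of the same treatments of the same set and are pseudo-replicates. The set 3 controls gave 9 genes for dual treatment in macrophages and 4 with against without galunisertib in T cells.

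With 1 unit left out, macrophages with against without galunisertib had 31 to 106 genes called, galunisertib alone 0, dual treatment 0 to 5, and T cells with against without 0 to 3. Median-of-ratios scaling gave 1 gene for galunisertib alone in macrophages and 3 in T cells with against without. It moved the median of all genes by -0.12 for dual treatment in T cells, and both interferon lists there are among the medians that changed sign. Without the filter on low values, where more genes are tested, galunisertib alone, dual treatment and T cells with against without each gave 0. A pseudocount of 16 gave 0 for galunisertib alone and 1 for dual treatment in macrophages. Leaving out clusters led by a marker of another type gave 0 for galunisertib alone in macrophages and 2 (Fxyd6 and Lpl) in fibroblasts with against without. Other counts stayed within 1.5 times the main count.

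With an estimated correlation 0 gene lists passed in every comparison without the block. With the block 8 lists in place of 4 passed for the interaction in macrophages. No TME class passed after adjustment under any alternative.

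In cells with at least 1000 UMIs and under 10% mitochondrial values CD8 T cells were 56.0% of the control library, 41.0% with anti-PD-L1, 54.1% with galunisertib and 51.1% in dual treatment. By the TRB CDR3 alone the share of cells in expanded clones was 77.8%, 71.2%, 72.1% and 80.4%, and for clones of at least 3 cells 70.3%, 59.8%, 63.3% and 70.7%, in the same order. The ratios of Tgfbr2 between the LysM libraries stayed within their interval. The planned fits for counts, a Wald test and another set of size factors, were not run, since the values are not counts. On simulated data the comparisons of 2 against 2 recovered 0% to 38% of genes with a log2 fold change of 1, and 50% to 86% with the set as a block.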

Other observations

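The tests of the library labelled knockout against the galunisertib genes were chosen only after the results were seen.

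Pmepa1 was lower with galunisertib in several types of the TME for which no gene test was planned. It stood at 2.90 ± 2.92 against 20.1 ± 1.85 CPM in neutrophils (SD, n = 4 each), at 30.8 ± 17.9 against 118 ± 53.8 in dendritic cells and at 53.7 ± 26.3 against 109.7 ± 34.6 in NK cells, and at 31.7 ± 11.8 against 29.7 ± 15.3 in B cells. In neutrophils and dendritic cells all 4 units with galunisertib lay below all 4 without. At the share that C1qa gives, free macrophage RNA would supply 87.6% of Pmepa1 in neutrophils without galunisertib, 5.44% in dendritic cells, 13.8% in NK cells and 30.4% in B cells, so the fall in neutrophils is not told apart from less free RNA. The set 3 controls held 52.4% macrophages or monocytes and 13.7% T cells.

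A hypothesis was that the macrophage genes that moved with galunisertib also move in the library whose label gives a loss of the receptor in myeloid cells. Tgfbr2 itself was not lower there (log2 ratio 0.39). Of the 92 genes that fell, 85 were measured in the LysM libraries, and 71 of them were lower in the library labelled knockout (median log2 ratio -0.59, percentile 0 among 10000 random lists of like expression, whose medians lay between -0.03 and 0.15). Of the 38 that rose, 31 were measured and 21 were higher (median 0.34, percentile 99.99). Both percentiles make no allowance for genes that move together. Apoe, F11r and Cx3cr1 were lower and Vcam1, Klf2 and Il6 higher in both, while Pmepa1 hardly moved (-0.10) and Skil (0.07), Cd9 (0.15), Cd38 (-0.31) and Mrc1 (-0.50) went the other way. With 1 library per genotype, any other difference between these libraries could give such a shift, so this stays a hypothesis.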
